A study of Mus musculus with 10 samples.

How the data were processed

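The data are 10 single-cell RNA libraries (10x 3' kit, version 3 chemistry, per the labels' protocols) of dorsal skin of female SKH-1 mice: 1 control, 1 UVR, and 2 each of UVR with 0.03% 9-cis HPR, 0.1% 9-cis HPR, 0.1% retinol or 0.1% retinoic acid. The skin was dissociated with collagenase, dispase and trypsin and sequenced on a NovaSeq 6000, per the labels' protocols. The dose and schedule of the ultraviolet exposure, and whether a library holds 1 animal, are not given in the sources used here. Per the file headers, the authors made the deposited counts (whole UMI counts per gene and cell barcode) with Cell Ranger 7.1.0. Reads were demultiplexed with bcl2fastq and mapped to mm10, per the submitters' processing notes. Every barcode had at least 500 UMIs. The files hold 55357 genes, of which 3276 are not in GENCODE vM21, the release used for coordinates.

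Libraries held 11211 to 29202 barcodes and 80577660 to 142980287 UMIs, and the 2 retinoic acid libraries had medians of 2613.0 and 10267.0 UMIs per barcode. Cells with at least 500 UMIs, 300 genes and at most 20% mitochondrial UMIs were kept, and doublets were scored against simulated doublets (2 per cell) and removed at 0.8% per 1000 barcodes, up to 10%. With scanpy 1.11.5 and leidenalg 0.10.2, 3000 cells per library were scaled to 10000 UMIs and reduced over 2000 variable genes to 30 principal components. They were clustered with 20 neighbours at resolution 1, and the remaining cells took the cluster of most of their 15 nearest neighbours. A cluster was named after the marker list, fixed before any count was read, with most markers among its 10 top genes and then the highest mean log2 fold (at least 0.25, or 1 with none among the 10) and at least 3 markers detected in 10% of its cells. A cluster with no own marker among the 10 and few UMIs per cell stayed unnamed, as did any meeting none. These limits were loosened after the data were seen.

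For basal keratinocytes, suprabasal keratinocytes and fibroblasts, counts were summed per library and tested with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM, quasi-likelihood F test on group with all 10 libraries in the fit, Benjamini-Hochberg adjusted p below 0.05. Every retinoid group was compared with UVR, 0.1% with 0.03% 9-cis HPR, and the 3 retinoids at 0.1% with each other. Fold changes are log2 ratios, and CPM are the class sums scaled by TMM library sizes, computed here from the deposited counts. Control and UVR have 1 library each, so they were set side by side with exact Poisson intervals and no test, a gene with 0 counts being placed at 3 counts, and list medians were ranked among 10000 random lists matched on abundance in 20 bins. On data simulated from these libraries, with 2-fold changes put into 100 genes and 1.5-fold changes into 100, the basal test recovered 89% and 65% against UVR. The fibroblast test recovered 79% and 45%. In all 4 runs with such changes false calls were above the 5% aimed at: 10 among 164 and 18 among 193 for basal and 12 among 136 and 22 among 195 for fibroblast tests (retinol against UVR and 9-cis HPR against retinol). Shares of each class were tested with edgeR's quasi-likelihood test on cell counts, with the library's cells as offset, over 14 classes and 8 comparisons.

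The 18 gene lists, fixed before any count was read, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with the correlation estimated: retinoid metabolism, dermal matrix, TGF-beta response, matrix proteases, basement membrane, epidermal differentiation, stress keratins and alarmins, inflammatory cytokines, interferon response, antigen presentation, immediate early and heat shock, p53 and DNA damage, antioxidant, senescence-associated, cell cycle, sterol synthesis, red cell and skeletal muscle genes. Whether a list changed differently in 2 classes was tested with limma on the per-library difference of its mean log2 CPM. Named genes are from the 5 largest rises and 5 largest falls among called genes of at least 20 CPM in 1 of the 2 groups, leaving out mitochondrial, ribosomal protein, Gm-numbered and Rik genes, with 1 to 4 members of a list. For UVR against control they are the 10 largest each way of at least 50 CPM whose intervals do not overlap. Which lists and which of their members each paragraph shows, and the genes placed on the genome, were picked after the values were seen, and a few genes are not reported here.

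The alternatives were RLE normalization, no low-count filter, DESeq2 1.42.0, no doublet removal, a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial), doubled resolution, equal cells per library, only the 2 groups compared, a replicate block, TMM factors for shares, leaving out each library in turn and, added later, only the largest cluster of each class (1, 2 and 5), shares without unnamed cells and a fit of the 8 numbered libraries. The other classes were used for shares only, and their genes were not tested. Genes in families of near-identical copies and antisense genes are marked as uncertain.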

Results

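Single-cell RNA libraries from dorsal skin of female SKH-1 mice were compared in untreated skin, ultraviolet-exposed (UVR) skin and UVR skin given 0.03% 9-cis HPR, 0.1% 9-cis HPR, 0.1% retinol or 0.1% retinoic acid, the last 2 being the positive controls of the design. The 10 libraries (1 control, 1 UVR and 2 for each retinoid group) kept 10042 to 26246 cells each, which fell into 26 clusters. Marker genes named 13 cell classes among them: Krt5- and Col17a1-bearing basal keratinocytes, Krt1- and Krt10-bearing suprabasal keratinocytes, Dpt- and Col14a1-bearing fibroblasts, cycling, follicle, immune, vascular, pigment and nerve-sheath cells. Names were withheld from 4.16% of control cells, 26.4% of UVR cells and 21.5% to 34.8% of the retinoid groups, with 47.4% in retinoic acid replicate 1 against 22.2% in replicate 2. Gene changes were tested in the basal, suprabasal and fibroblast classes on counts summed per library (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05), and are given as log2 fold changes. List counts are over all genes, and those adjusted over the list alone follow where they differ. No gene list kept its call when the correlation between its genes was estimated (lowest adjusted p = 0.0679). The common biological coefficient of variation was only 4.35%, 4.96% and 6.37%, on 4 residual degrees of freedom. Every p-value therefore measures only the spread between these samples, which may be technical, and the lone UVR library is assumed to vary like the others.

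How ultraviolet exposure altered skin was asked from 1 control and 1 UVR library, so values (CPM, control to UVR) are given with no test. Basal keratinocytes of UVR skin carried more stress keratin, alarmin and interferon response RNA and less differentiation RNA. The chemokine Ccl8 (2.51 to 1016) was higher in UVR, as were Il24 (1.10 to 63.7), Car2 (2.02 to 194) and the pore-forming gasdermins Gsdmc (0.973 to 109) and Gsdmc2 (0.666 to 91.6). Members of multigene families, whose reads are hard to assign, led the increase: Chil4 (9140 counts against 0, at least 9572-fold over a floor of 3 counts per library), Sprr2a3 (4.92 to 2432), Sprr2d (0.768 to 121), Krt6b (1.61 to 183) and Csta3 (0.563 to 54.4). Lower in UVR were the keratins Krt10 (2033 to 140.1) and Krt77 (82.0 to 1.77) of interfollicular epidermis and Dapl1 (174 to 6.27), Sema3d (119 to 1.93), Akr1c18 (76.0 to 3.30), Efemp1 (70.2 to 4.10), Creb5 (69.7 to 4.67), Serpinb7 (57.5 to 0.563), Zbtb16 (56.3 to 2.65) and Hmcn1 (53 to 2.17). Against 10000 random lists of matched abundance, interferon response genes (median 1.80, percentile 100), stress keratins and alarmins (median 2.77, percentile 100) and cell cycle genes (median 1.16, percentile 100) were among those above and epidermal differentiation genes (median -0.95, percentile 0) among those below. The immediate early and heat shock list, which also follows handling of the tissue, lay below nearly all of them (median -0.57). In all, 163 genes were at least 2-fold higher and 190 lower with counting intervals apart. Different clusters held the class: clusters 11 and 18 had 69.0% and 30.2% of control basal cells, and cluster 1 had 98.9% of those in UVR.

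In suprabasal keratinocytes RNA of cornified-envelope genes was far lower after exposure. The filaggrin relative Flg2 (1819 counts against 0, at least 5679-fold over a floor of 3 counts per library) was lost, with Wfdc21 (850 counts against 0, at least 2654-fold over a floor of 3 counts per library), Kprp (353 counts against 1, 3306-fold, interval 589.5 to 130950) and Krt77 (11620 to 5.96). The late cornified envelope family went the same way, with assignment between members uncertain: Lce1a1 (2614 counts against 1, 24482-fold, interval 4390.1 to 967340), Lce1b (2197 counts against 0, at least 6859-fold over a floor of 3 counts per library) and, at 0 or 1 counts in UVR, Lce1c, Lce1a2, Lce1f and Lce1m. Higher in UVR were Stom (10.7 to 181), Mgst1 (11.5 to 177), Parp8 (4.11 to 109), the prostaglandin D2 synthase Hpgds (3.28 to 81.2), the interleukin 4 and 13 receptor Il4ra (3.28 to 52.4), Ass1 (681 counts against 2, 36.4-fold, interval 10.0 to 301) and Ccl8 (7615 counts against 3, 271-fold, interval 92.7 to 1314), next to the multigene members Stfa2 (6.57 to 220.4), Sprr2a3 (243 to 7155) and Chil4 (10127 counts against 0, at least 360.4-fold over a floor of 3 counts per library). Epidermal differentiation (median -3.25, percentile 0), retinoid (median -1.35, percentile 0.0700) and sterol and fatty acid genes (median -1.18, percentile 0.0200) were among those below the random lists, and cell cycle (median 2.37, percentile 100), inflammatory (median 1.23, percentile 100) and antioxidant genes (median 0.76, percentile 99.9) among those above. In total 365 genes were at least 2-fold higher and 694 lower. Control gave only 95 suprabasal cells, 80.0% of them in cluster 13 (marked by Cnfn and Crct1) against 7.63% of the 904 UVR cells, so different suprabasal cells were compared.

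Fibroblasts of UVR skin had less TGF-beta response RNA. Lower were Igfbp5 (3471 to 366), Igfbp2 (926 to 125), the retinoic acid-degrading Cyp26b1 (605 to 88.5), the bone morphogenetic protein blocker Grem1 (78.1 to 3.04), Fam180a (110 to 9.13), Tmem132c (81.0 to 9.13), Efhd1 (76.1 to 11.9), Stc1 (66.2 to 1.01), Sema3a (53 to 8.12) and F13a1 (282 counts against 0, at least 95.9-fold over a floor of 3 counts per library). The lubricant Prg4 (3.36 to 80.1) was higher. The endothelial Fabp4 (25.1 to 274) and multigene and keratinocyte transcripts were higher too (stress keratins and alarmins at 15.03 UMIs per cell in UVR fibroblasts and 13.72 in UVR endothelium): Krt6a (11.1 to 312), Krt6b (305 counts against 3, 99.6-fold, interval 33.8 to 486), Sprr1b (4.92 to 63.6), Stfa3 (18.4 to 549), Cstdc5 (16.6 to 691), Sprr2a3 (1218 counts against 0, at least 398-fold over a floor of 3 counts per library) and Chil4 (230 counts against 0, at least 75.1-fold over a floor of 3 counts per library). Stress keratins and alarmins (median 2.06, percentile 100), interferon response (median 0.63, percentile 100) and cell cycle genes (median 0.92, percentile 100) were among those above the random lists, TGF-beta response (median -0.43, percentile 0) and senescence-associated genes (median -0.25, percentile 0.200) among those below, and dermal matrix genes within them (median -0.01, percentile 9.44). Genes at least 2-fold apart numbered 131 higher and 78 lower. Cluster 16, marked by Crabp1, Tnn, Igfbp2, Cilp and Cyp26b1, held 46.8% of control and 17.8% of UVR fibroblasts, so the loss goes with a shift between kinds of fibroblast.

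How the make-up of the skin differed was asked from the share of each class among kept cells. Basal keratinocytes made up 50.03% (95% exact interval 49.16 to 50.9) of control and 11.65% (11.04 to 12.29) of UVR cells, and suprabasal keratinocytes 0.740% (0.599 to 0.904) and 8.78% (8.24 to 9.34); dissociation can set such shares, and this pair had no test. Unnamed cluster 0, nearest to basal keratinocytes, held 2.90% (2.62 to 3.21) of control and 14.4% (13.8 to 15.1) of UVR cells, and cluster 10 rose likewise, so part of the drop may rest on naming. Retinoic acid raised suprabasal keratinocytes (2.23-fold, log2 1.16 ± 0.31 SE, adjusted p = 0.00136) and cycling cells (1.68-fold) over UVR skin and lowered fibroblasts (0.393-fold, log2 -1.35 ± 0.29 SE, adjusted p = 9.71e-05), melanocytes (0.165-fold), Schwann cells (0.107-fold), follicle keratinocytes (0.239-fold), lymphatic endothelium (0.298-fold), blood endothelium (0.367-fold) and pericytes (0.452-fold), the last 2 not passing when shares were scaled by TMM factors. Retinol raised T, NK or innate lymphoid cells (2.17-fold, log2 1.12 ± 0.31 SE, adjusted p = 0.002), which clusters 6, 14 and 20 held in treated skin, neutrophils (2.22-fold), Langerhans or macrophage cells (1.94-fold), blood endothelium (1.81-fold) and suprabasal keratinocytes (1.65-fold), and lowered cycling cells (0.580-fold), melanocytes (0.535-fold), follicle keratinocytes (0.245-fold) and Schwann cells (0.341-fold). At 0.03%, 9-cis HPR raised neutrophils (3.09-fold) and Langerhans or macrophage cells (2.14-fold) and lowered cycling cells (0.459-fold), melanocytes (0.386-fold), follicle keratinocytes (0.458-fold) and Schwann cells (0.372-fold). At 0.1%, 9-cis HPR differed from UVR only in blood endothelium (0.578-fold), melanocytes (0.607-fold) and neutrophils (1.86-fold), and each of these failed without any 1 of 6 libraries (0.03% 9-cis HPR, 0.1% 9-cis HPR or retinol, log2 -0.83 to -0.75, -0.78 to -0.67 and 0.88 to 0.91).

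**Figure D1:**
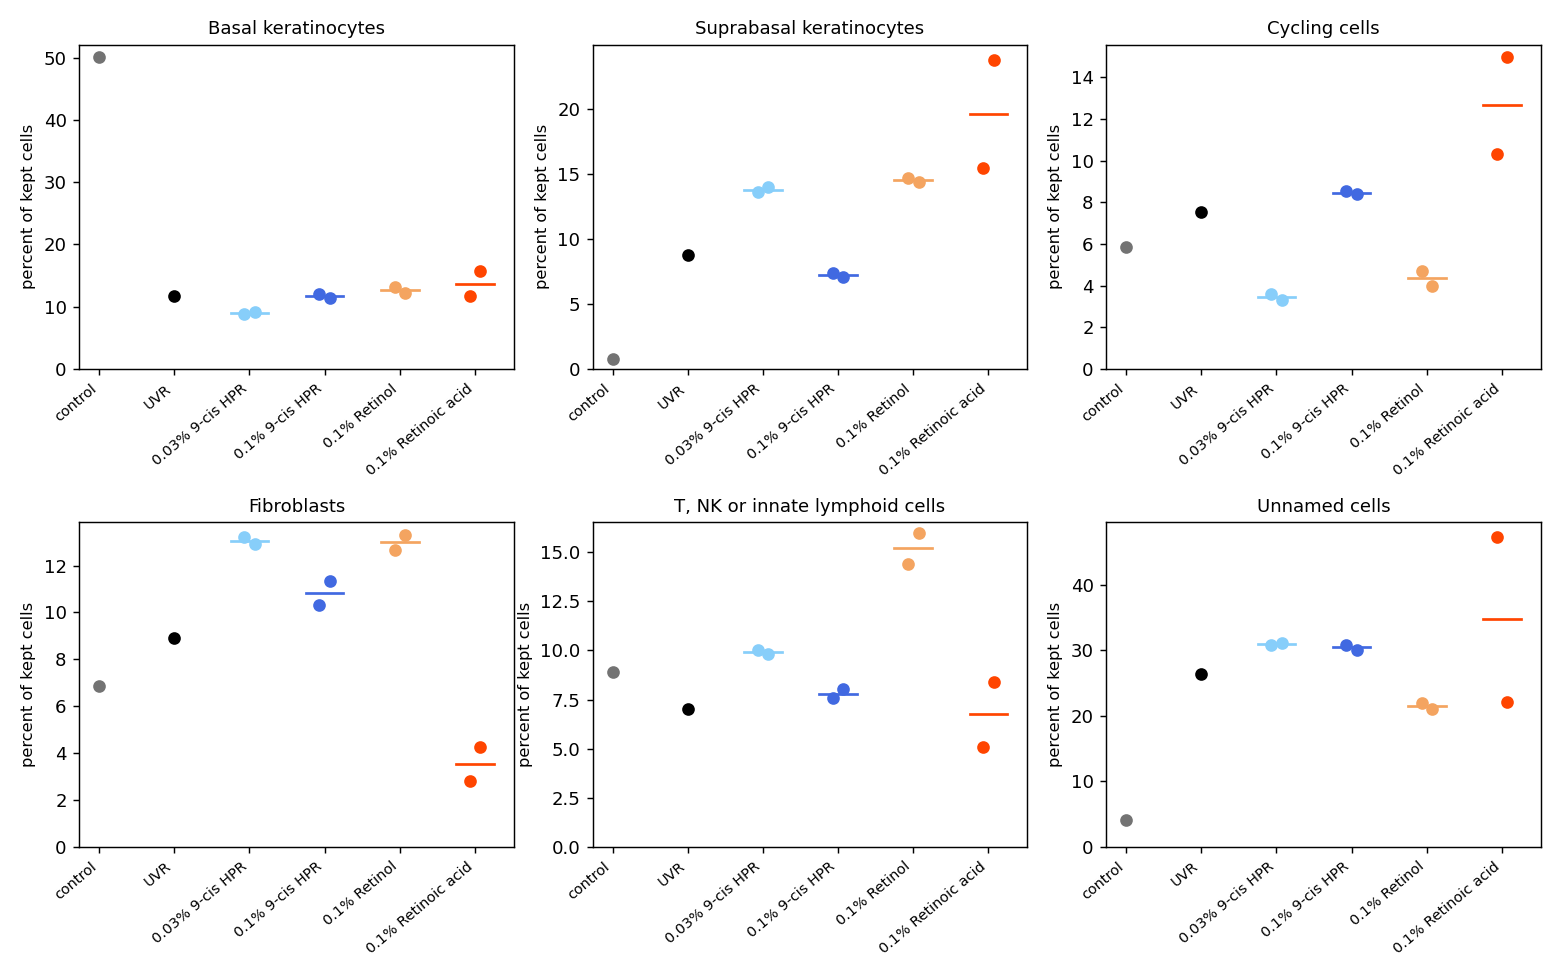
Percent of kept cells in 6 classes, 1 point per library by group, lines marking the mean of 2 libraries. Unnamed cells were 47.4% and 22.2% of the 2 retinoic acid libraries.

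Among the calls between retinoid groups, cycling cells were 2.46-fold more common at 0.1% than at 0.03% 9-cis HPR (adjusted p = 1.33e-05) and suprabasal keratinocytes fewer (0.524-fold). Against retinol at the same dose, 0.1% 9-cis HPR held more follicle keratinocytes (2.95-fold) and fewer T, NK or innate lymphoid cells (0.513-fold), blood endothelial cells (0.320-fold) and suprabasal keratinocytes (0.497-fold). Against retinoic acid it held more fibroblasts (3.10-fold), melanocytes (3.68-fold), Schwann cells (6.37-fold), pericytes (3.07-fold), lymphatic endothelium (3.22-fold) and follicle keratinocytes (3.03-fold) and fewer suprabasal keratinocytes (0.368-fold). Retinoic acid held fewer fibroblasts (0.269-fold), blood endothelial cells (0.203-fold), lymphatic endothelial cells (0.177-fold), melanocytes (0.308-fold) and pericytes (0.359-fold) than retinol and more cycling cells (2.90-fold). For basal keratinocytes no comparison passed, with intervals as wide as log2 -0.96 to 0.21 (0.03% 9-cis HPR over UVR) and -0.36 to 0.82 (retinoic acid over UVR). Of 112 tests of a share, 66 passed, 39 of them between retinoid groups (44 to 100 passed without 1 library).

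What 0.03% 9-cis HPR changed in UVR skin was asked first in basal keratinocytes, which lost proliferation and DNA damage transcripts and gained the skin-homing chemokine Ccl27a. Among the largest falls were Serpine2 (-3.23 ± 0.24 SE, adjusted p = 6.03e-09, 3.32 against 31.1 CPM), a serine protease inhibitor, and Ptp4a3, Kitl and Sulf2 (-2.35 to -1.60). The largest rises were Ccl27a (1.90 ± 0.12 SE, adjusted p = 8.21e-10, 493 against 132 CPM) and Chit1, Il11ra1, Igfbp3 and Col1a2 (1.49 to 1.96). Cell cycle genes fell (16 of 22 lower, 0 higher and 6 not passing, 18 and 0 adjusted over the list alone, camera adjusted p = 7.42e-13, adjusted p = 0.179 with an estimated correlation), with Rrm2 (-1.05), Cdk1 (-1.05) and Birc5 (-0.96). P53 and DNA damage genes (10 of 18 lower, 0 higher and 8 not passing, 12 and 1 adjusted over the list alone) included Ccng1 (-0.93), Aen (-0.71) and Bax (-0.59). Inflammatory cytokine genes also declined (12 of 22 lower, 2 higher and 8 not passing, 14 and 3 adjusted over the list alone), with Tnf (-1.33), Ccl20 (-0.91) and Ptgs2 (-0.91), although the list mean was 0.07. Most retinoid genes did not pass (5 of 15 lower, 1 higher and 9 not passing). Dermal matrix RNA also differed in these cells (6 of 25 higher, 2 lower and 17 not passing, 7 and 2 adjusted over the list alone). In all, 2718 of 15569 genes passed (1226 higher and 1492 lower, 179 and 278 of them by at least 2-fold, 1714 without 0.03% 9-cis HPR replicate 1, 1768 without replicate 2).

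Suprabasal keratinocytes given 0.03% 9-cis HPR had less cell cycle RNA and more RNA of some epidermal differentiation genes (10 of 24 higher, 2 lower and 12 not passing, 13 and 2 adjusted over the list alone). Rises were Krt77 (3.38 ± 0.13 SE, adjusted p = 6.56e-11, 62.0 against 5.96 CPM), the cornified-envelope genes Crct1 (2.19), Lor (1.86) and Flg (1.70) and the red cell transcript Hbb-bs (5.55). Falls were Dcxr (-2.37 ± 0.14 SE, adjusted p = 1.33e-08, 6.55 against 33.8 CPM) and Ptp4a3, Sulf2, Tubb3 and Car2 (-2.09 to -1.63). Cell cycle genes fell (17 of 22 lower, 0 higher and 5 not passing, 19 and 0 adjusted over the list alone, camera adjusted p = 1.07e-13, adjusted p = 0.278 with an estimated correlation), with Cdk1 (-1.68), Mcm5 (-1.68) and Stmn1 (-1.32). Alarmins and stress keratins split (6 of 17 lower, 5 higher and 6 not passing, 7 and 6 adjusted over the list alone), with Krt6b (-0.95) and Krt6a (-0.93), which are hard to tell apart, among the lower. Altogether 2631 of 15426 genes passed (1284 higher and 1347 lower, 182 and 325 of them by at least 2-fold, 1714 without 0.03% 9-cis HPR replicate 1, 1604 without replicate 2). Hbb-bs (4.96) did not pass without 0.03% 9-cis HPR replicate 1. With 95 cells from every library Lor (-2.26) and Flg (-1.93) turned direction and did not pass, and in cluster 2 alone Lor (0.60) did not pass.

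In fibroblasts, 0.03% 9-cis HPR brought more dermal matrix, interferon response and inflammatory RNA. Rises were the nerve growth factor receptor Ngfr (5.30 ± 0.36 SE, adjusted p = 2.71e-07, 50.5 against 1.27 CPM), the hyaluronan synthase Has2 (3.09), the progesterone receptor Pgr (4.82), Ptpn5 (954 counts against 1, 177-fold, interval 31.7 to 7009) and Krt23 (533 counts against 1, 99.0-fold, interval 17.7 to 3919). Falls were Fmod (-2.45 ± 0.24 SE, adjusted p = 9.38e-06, 10.3 against 56.3 CPM), Myoc, Ednrb and Mmp13 (-2.38 to -2.10) and Coch (-5.06), the last -0.21 and not passing in cluster 5 alone. Dermal matrix genes (14 of 26 higher, 3 lower and 9 not passing, 14 and 4 adjusted over the list alone, camera adjusted p = 5.97e-07, adjusted p = 0.524 with an estimated correlation) included Fbn1 (1.06), Col3a1 (0.96) and Col1a2 (0.95) higher. Interferon response genes rose (13 of 21 higher, 0 lower and 8 not passing, 18 and 0 adjusted over the list alone), with Rsad2 (2.55) and Isg15 (1.72). Inflammatory genes (12 of 22 higher, 1 lower and 9 not passing, 14 and 1 adjusted over the list alone) included Il33 (1.82), Ccl2 (1.48) and Cxcl1 (1.33). TGF-beta response genes split (4 of 16 lower, 3 higher and 9 not passing, 5 and 4 adjusted over the list alone), with Ccn2 (-1.83), Tgfbi (-1.59) and Tgfbr2 (0.95). In fibroblasts 2154 of 15592 genes passed (1244 higher and 910 lower, 327 and 376 of them by at least 2-fold, 1346 without 0.03% 9-cis HPR replicate 1, 1404 without replicate 2). Cluster 16 held 9.54% of these fibroblasts. Mmp13 (-2.10 to -1.38) did not pass without 0.03% 9-cis HPR replicate 2 or either 0.1% Retinol library. Mmp13 (-3.61) and Coch (-4.43) without 0.03% 9-cis HPR replicate 1 and Coch (-6.15) without 0.03% 9-cis HPR replicate 2 moved by more than 1.5-fold.

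What the higher 0.1% dose of 9-cis HPR changed in UVR skin was asked next, and basal keratinocytes lost interferon and immediate early transcripts. They lost Serpine2 (-2.79 ± 0.21 SE, adjusted p = 9.25e-09, 4.49 against 31.1 CPM), the Notch target Hes1 (-1.67), Ptp4a3 and Cd55 (-1.84 to -1.58) and the multigene Stfa2 (-1.60). They gained Dapl1 (2.09 ± 0.17 SE, adjusted p = 2.44e-08, 26.7 against 6.27 CPM), Chit1, Abcc3 and Cdh13 (1.47 to 1.88) and Col1a1 (1.39). Interferon response genes fell (10 of 21 lower, 0 higher and 11 not passing, 13 and 0 adjusted over the list alone, camera adjusted p = 4.32e-10, adjusted p = 0.0992 with an estimated correlation), with Ifit1 (-1.68), Oas1a (-1.34) and Bst2 (-1.19). Immediate early and heat shock genes (7 of 19 lower, 0 higher and 12 not passing, 9 and 2 adjusted over the list alone), which also follow handling, were led by Fosb (-0.82) and Fos (-0.56). No basement membrane gene passed (0 of 15 higher, 0 lower and 15 not passing, 3 and 3 adjusted over the list alone), with a list mean of 0.08 and a median just below 0. Dermal matrix RNA rose in these cells (17 of 25 higher, 1 lower and 7 not passing, 18 and 2 adjusted over the list alone). In total 787 of 15569 genes passed (370 higher and 417 lower, 100 and 86 of them by at least 2-fold, 476 without 0.1% 9-cis HPR replicate 1). Oas1a (-1.43 to -1.25) did not pass without either 0.1% 9-cis HPR library.

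At 0.1%, 9-cis HPR changed fewer suprabasal genes than 0.03% did. Lor, the main cornified-envelope protein, increased (2.60 ± 0.37 SE, adjusted p = 0.000397, 44.6 against 7.28 CPM), with Krt77, Sparc and Col1a2 (1.44 to 1.99) and the multigene Chil4 (1.57). The sharpest falls were Dcxr (-1.91 ± 0.14 SE, adjusted p = 5.96e-07, 8.99 against 33.8 CPM) and Il19, Ptp4a3, Sulf2 and Ccl8 (-1.45 to -1.17). Stress keratins and alarmins split (4 of 17 higher, 2 lower and 11 not passing, 5 and 4 adjusted over the list alone), with S100a8 (1.19) and S100a9 (1.13) higher and Krt6a (-0.48) and Krt16 (-0.42) lower. Dermal matrix RNA rose here too (8 of 25 higher, 0 lower and 17 not passing, 19 and 1 adjusted over the list alone, camera adjusted p = 2.18e-13, adjusted p = 0.293 with an estimated correlation), with Col6a3 (2.11) and Fn1 (1.53). In suprabasal cells 470 of 15426 genes passed (208 higher and 262 lower, 61 and 51 of them by at least 2-fold, 298 without 0.1% 9-cis HPR replicate 2). Krt16 (-0.35) did not pass without 0.1% 9-cis HPR replicate 1, nor did Col6a3 (2.06) without 0.1% 9-cis HPR replicate 2, or Fn1 (1.40 to 1.64) without either 0.03% 9-cis HPR library or either 0.1% 9-cis HPR library. With 95 cells per library Il19 turned direction (0.77) and did not pass, and in cluster 2 alone Lor (0.63) did not pass.

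Fibroblasts given 0.1% 9-cis HPR gained RNA of TGF-beta response genes, a list lower in UVR than in control skin, and of some dermal matrix genes. Cyp26b1, which breaks down retinoic acid, increased (2.40, 468 against 88.5 CPM), as did Grem1 (5.04 ± 0.24 SE, adjusted p = 3.43e-08, 100.3 against 3.04 CPM), Stc1, Reg3g and Ccl19 (2.52 to 5.13) and F13a1 (365 counts against 0, at least 27.4-fold over a floor of 3 counts per group). They lost Igfbp3 (-1.80 ± 0.15 SE, adjusted p = 4.69e-06, 357 against 1241 CPM) and Plcxd3, Hhip, Fam13a and Inmt (-2.25 to -1.73). TGF-beta response genes rose (8 of 16 higher, 0 lower and 8 not passing, 8 and 1 adjusted over the list alone, camera adjusted p = 5.18e-06, adjusted p = 0.359 with an estimated correlation), led by Tagln (2.05), Ltbp2 (2.03), Tgfb1 (1.09) and Acta2 (0.93). Dermal matrix genes (9 of 26 higher, 0 lower and 17 not passing, 19 and 1 adjusted over the list alone) included Eln (0.96), Mfap4 (0.87) and Bgn (0.61). Matrix proteases and inhibitors (3 of 20 higher, 0 lower and 17 not passing, 3 and 2 adjusted over the list alone) included Timp1 (1.04), and senescence-associated genes (6 of 16 higher, 2 lower and 8 not passing, 7 and 2 adjusted over the list alone) included Igfbp2 (1.97) and Igfbp5 (1.32). In fibroblasts 905 of 15592 genes passed (456 higher and 449 lower, 164 and 114 of them by at least 2-fold, 539 without 0.1% 9-cis HPR replicate 1, 543 without replicate 2, 1373 without 0.1% Retinoic acid replicate 1). Cluster 16 held 41.9% of these fibroblasts, and in cluster 5 alone Tagln (0.62), Ltbp2 (1.16), Tgfb1 (0.71), Eln (0.29), Bgn (0.38), Ccl19 (0.83), Igfbp2 (1.41), Acta2 (-0.44) and F13a1 did not pass, while Cyp26b1 (2.27) and Mfap4 (0.84) did. Acta2 (0.82) did not pass without 0.1% 9-cis HPR replicate 1.

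What 0.1% retinol, a positive control, changed in UVR skin was asked next, and basal keratinocytes had more interferon response RNA and less RNA of some differentiation genes. The calprotectin subunits S100a9 (2.40 ± 0.12 SE, adjusted p = 1.18e-11, 181 against 34.3 CPM) and S100a8 (2.06) increased, with Isg15, Mmp3 and Col1a1 (1.58 to 1.62). Falls were led by Serpine2 (-2.88 ± 0.21 SE, adjusted p = 2.71e-09, 4.21 against 31.1 CPM) and Mt4, Sbsn and Them5 (-2.80 to -1.92). Interferon response genes rose (11 of 21 higher, 0 lower and 10 not passing, 15 and 1 adjusted over the list alone, camera adjusted p = 2.73e-09, adjusted p = 0.0992 with an estimated correlation), with Usp18 (2.2) and Ifi44 (1.98). Epidermal differentiation genes (7 of 24 lower, 1 higher and 16 not passing, 10 and 2 adjusted over the list alone) included Krt2 (-3.28) and Krt10 (-1.13). Basement membrane genes (9 of 15 higher, 1 lower and 5 not passing, 11 and 1 adjusted over the list alone) included Col7a1 (0.58). Dermal matrix RNA rose alongside (15 of 25 higher, 2 lower and 8 not passing, 16 and 2 adjusted over the list alone). Stress keratins and alarmins as a list went both ways (5 of 17 higher, 3 lower and 9 not passing, 5 and 5 adjusted over the list alone). Among retinoid genes Hbegf rose (0.32), and Lrat (-1.37) and Crabp2 (-1.06) fell. In this class 1726 of 15569 genes passed (898 higher and 828 lower, 196 and 232 of them by at least 2-fold, 1089 without 0.1% Retinol replicate 2). Ifi44 (1.46) did not pass without 0.1% Retinol replicate 1, nor did Hbegf (0.21) without 0.1% Retinol replicate 2. Mt4 (-3.55) without 0.1% Retinol replicate 1 moved by more than 1.5-fold.

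Suprabasal keratinocytes given retinol lost cell cycle RNA and gained part of the stress keratin and alarmin list. Rises were S100a9 (3.83 ± 0.16 SE, adjusted p = 1.14e-10, 1745 against 122 CPM), S100a8 and Defb3 (2.92 to 3.42), the multigene Sprr2b (2.51) and Hbb-bs of red cells (4.84). Falls were Mt4 (-2.54 ± 0.18 SE, adjusted p = 9.28e-08, 27.2 against 157 CPM), an epidermal metallothionein, and Dcxr, Sulf2, Stmn1 and Gstp1 (-2.26 to -1.73). Cell cycle genes fell (16 of 22 lower, 0 higher and 6 not passing, 19 and 0 adjusted over the list alone, camera adjusted p = 7.55e-14, adjusted p = 0.278 with an estimated correlation), with Ube2c (-1.45) and Ccnb2 (-1.40). Alarmins and stress keratins (9 of 17 higher, 0 lower and 8 not passing) included Lcn2 (1.96). Antigen presentation genes (5 of 14 higher, 3 lower and 6 not passing, 5 and 5 adjusted over the list alone) included Cd74 (1.38) and H2-Ab1 (0.93), which Langerhans cells also make. Dermal matrix RNA rose in these cells (16 of 25 higher, 1 lower and 8 not passing, 19 and 1 adjusted over the list alone). Altogether 2151 of 15426 genes passed (1088 higher and 1063 lower, 250 and 312 of them by at least 2-fold). Hbb-bs (3.78 to 4.84) did not pass without 0.1% Retinol replicate 1 or either 0.1% Retinoic acid library.

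In fibroblasts, retinol raised part of the dermal matrix list and moved TGF-beta response genes both ways. Akr1c18, which inactivates progesterone, increased (3.03 ± 0.13 SE, adjusted p = 8.98e-09, 243 against 29.7 CPM), with Ngfr and Pgr (3.24 to 4.53), the keratinocyte alarmin S100a9 (3.40) and Mrgprg (668 counts against 0, at least 38.2-fold over a floor of 3 counts per group). Losses were Fmod (-2.64 ± 0.25 SE, adjusted p = 5.96e-06, 8.91 against 56.3 CPM), Gldn, Hhip and Rasd1 (-3.57 to -2.62) and Coch (-4.63, and -0.90 without passing in cluster 5 alone). Dermal matrix genes (13 of 26 higher, 4 lower and 9 not passing, 15 and 6 adjusted over the list alone, camera adjusted p = 0.000118, adjusted p = 0.594 with an estimated correlation) included Fbn1 (1.06), Mfap5 (0.79) and Fn1 (0.75) among the rises. TGF-beta response genes (5 of 16 lower, 3 higher and 8 not passing, 7 and 3 adjusted over the list alone) included Ccn2 (-2.10), Acta2 (-0.98) and Tagln (-0.94). In fibroblasts 1620 of 15592 genes passed (828 higher and 792 lower, 228 and 357 of them by at least 2-fold). Cluster 16 held 6.85% of these fibroblasts. Acta2 (-0.68) did not pass without 0.1% Retinol replicate 2, nor did Tagln (-0.94 to -0.59) without either 0.03% 9-cis HPR library or 0.1% Retinol replicate 2. Fmod (-3.28) and Coch (-4.02) without 0.1% Retinol replicate 1 and Coch (-5.59) without 0.1% Retinol replicate 2 moved by more than 1.5-fold.

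What 0.1% retinoic acid changed in UVR skin included some known targets of its receptors. Basal keratinocytes raised Tslp (4.22 ± 0.16 SE, adjusted p = 3.85e-14, 389 against 20.8 CPM), a cytokine that alerts dendritic and lymphoid cells, and S100a9, S100a8, Hs3st1 and Tnfaip2 (3.03 to 4.93). Stra6, an importer of retinol and a retinoic acid target, increased (5.02 ± 0.35 SE, adjusted p = 4.78e-10, 15.8 against 0.483 CPM), as did Cyp26b1 (1.23) and Dhrs9 (1.5). Falls included Serpine2, Sulf2, Ptp4a3 and Ppp2r2c (-3.39 to -2.31). The other retinoid genes mostly did not pass (5 of 15 higher, 2 lower and 8 not passing, 6 and 2 adjusted over the list alone). Stress keratins and alarmins rose (12 of 17 higher, 0 lower and 5 not passing, 13 and 1 adjusted over the list alone, camera adjusted p = 1.34e-10, adjusted p = 0.253 with an estimated correlation). Interferon response genes (9 of 21 lower, 0 higher and 12 not passing, 12 and 0 adjusted over the list alone) included Ifit1 (-1.68) and Stat2 (-0.97). Dermal matrix RNA fell in these cells (16 of 25 lower, 1 higher and 8 not passing, 18 and 1 adjusted over the list alone), with Col3a1 (-1.91). In this class 3625 of 15569 genes passed (2059 higher and 1566 lower, 352 and 484 of them by at least 2-fold). Col3a1 (-2.55) without 0.1% Retinoic acid replicate 1 moved by more than 1.5-fold.

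Retinoic acid raised RNA of epidermal differentiation and of sterol genes in suprabasal keratinocytes. Involucrin RNA rose (3.19 ± 0.21 SE, adjusted p = 9.06e-09, 27.2 against 2.98 CPM), as did the desquamation protease Klk7 (2.43), S100a9 and S100a8 (4.26 to 5.09) and the late cornified envelope members Lce3c, Lce3f and Lce3d (4.59 to 5.33), whose reads are hard to part. Falls were Dcxr (-2.88 ± 0.14 SE, adjusted p = 3.59e-10, 4.64 against 33.8 CPM) and Igfbp2, Col3a1, Ptp4a3 and Sulf2 (-2.04 to -1.85). Epidermal differentiation genes (16 of 24 higher, 3 lower and 5 not passing, camera adjusted p = 1.88e-08, adjusted p = 0.278 with an estimated correlation) included Alox12b (2.06) higher and Krt2 (-3.77) lower. Sterol and fatty acid genes rose (14 of 18 higher, 0 lower and 4 not passing, 15 and 0 adjusted over the list alone), led by Scd2 (1.97), Cyp51 (1.10) and Lss (1.01). Retinoid genes (8 of 15 higher, 2 lower and 5 not passing) included Stra6 (666 counts against 3, 41.3-fold, interval 14.1 to 201) and Aldh1a3 (1.91) and Cyp26b1 (1.25). The antioxidant list (7 of 20 lower, 4 higher and 9 not passing, 9 and 5 adjusted over the list alone) included Slc7a11 (2.79) and Gsta4 (1.51) among its rises. In all, 3768 of 15426 genes passed (2016 higher and 1752 lower, 462 and 490 of them by at least 2-fold). Cluster 13 held 34.6% of these cells, and in cluster 2 alone Alox12b was 0.21 and did not pass, while Ivl (2.74), Klk7 (1.43) and Scd2 (0.66) did.

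Fibroblasts given retinoic acid lost matrix RNA and carried keratinocyte alarmins. Dermal matrix genes fell (12 of 26 lower, 0 higher and 14 not passing, 16 and 1 adjusted over the list alone, camera adjusted p = 3.11e-12, adjusted p = 0.372 with an estimated correlation), with Fmod (-2.25), Mfap4 (-1.24) and Col3a1 (-0.75). Other falls were Myoc (-3.77 ± 0.26 SE, adjusted p = 9.78e-07, 12.9 against 182 CPM) and Esm1, Ecrg4 and Cntn1 (-3.58 to -2.67). The retinoic acid receptor gene Rarb rose (1.53), with Dhrs9 (1.59) and Aldh1a3 (1.56), amid the wider retinoid list (5 of 18 higher, 0 lower and 13 not passing, 7 and 1 adjusted over the list alone). Rises were led by Mrgprg (253 counts against 0, at least 83.7-fold over a floor of 3 counts per group) and the keratinocyte transcripts S100a9, S100a8 and Serpinb2 (3.56 to 6.18) and Sprr2g (3.63). Alarmins and stress keratins (13 of 17 higher, 0 lower and 4 not passing) and epidermal differentiation genes (11 of 19 higher, 0 lower and 8 not passing, 15 and 0 adjusted over the list alone) thus moved inside a dermal class. In fibroblasts 1212 of 15592 genes passed (593 higher and 619 lower, 234 and 221 of them by at least 2-fold). Cluster 21, of 1144 median UMIs, held 27.3% of these fibroblasts. Rarb (1.00 to 1.53) did not pass without either 0.03% 9-cis HPR library, either 0.1% 9-cis HPR library, either 0.1% Retinol library or 0.1% Retinoic acid replicate 2. Myoc (-4.56), Esm1 (-4.25) and Cntn1 (-3.99) without 0.1% Retinoic acid replicate 2 and Cntn1 (-2.08) without 0.1% Retinoic acid replicate 1 moved by more than 1.5-fold.

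Whether the dose of 9-cis HPR mattered was asked by setting 0.1% against 0.03%. Basal keratinocytes carried more cell cycle RNA and less interferon RNA at the higher dose. Rises were the activin blocker Fst (1.29 ± 0.10 SE, adjusted p = 6.28e-09, 118 against 48.3 CPM) and Il24, Abcc3, Serpinb2 and Tm4sf1 (1.25 to 1.80). Falls were Ccl8 (-1.13 ± 0.06 SE, adjusted p = 1.24e-10, 462 against 1014 CPM) and Ifi27l2a, Kcnk2, Il11ra1 and Mir205hg (-1.29 to -1.03). Cell cycle genes rose (18 of 22 higher, 0 lower and 4 not passing, 20 and 0 adjusted over the list alone, camera adjusted p = 3.72e-15, adjusted p = 0.168 with an estimated correlation), with Cdk1 (0.96), Mcm5 (0.95) and Mcm3 (0.90). Interferon response genes (9 of 21 lower, 1 higher and 11 not passing, 10 and 1 adjusted over the list alone) included Isg15 (-1.34). The skeletal muscle list had 2 measured members (1 of 2 higher, 0 lower and 1 not passing). In this class 3182 of 15569 genes passed (1656 higher and 1526 lower, 205 and 100 of them by at least 2-fold, 1731 without 0.03% 9-cis HPR replicate 1, 1835 without replicate 2, 2082 without 0.1% 9-cis HPR replicate 1).

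In suprabasal keratinocytes the higher dose of 9-cis HPR likewise came with more cycling RNA. Rises were the nucleotide enzyme Dut (1.22 ± 0.19 SE, adjusted p = 0.000298, 27.0 against 11.6 CPM), the tubulins Tubb3 and Tubb5 (0.99 to 1.32) and Mt4 and Dcn (0.92 to 1.04). Falls were Krt77 (-1.39 ± 0.07 SE, adjusted p = 1.13e-08, 23.6 against 62.0 CPM), Ccl8 and H2bc4 (-1.01 to -0.92), the multigene Sprr2a1 (-1.08) and Tsix (-1.07), which lies antisense to Xist and is uncertain. The cell cycle list (15 of 22 higher, 0 lower and 7 not passing, 18 and 0 adjusted over the list alone, camera adjusted p = 1.24e-11, adjusted p = 0.293 with an estimated correlation) included Cdk1 (1.30), Mcm5 (1.10) and Ccna2 (1.04). Dermal matrix RNA was higher (11 of 25 higher, 0 lower and 14 not passing, 12 and 0 adjusted over the list alone). Altogether 2523 of 15426 genes passed (1224 higher and 1299 lower, 230 and 59 of them by at least 2-fold, 1244 without 0.03% 9-cis HPR replicate 1, 1018 without replicate 2, 1205 without 0.1% 9-cis HPR replicate 1, 1667 without replicate 2).

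Fibroblasts at the higher dose of 9-cis HPR had more TGF-beta response RNA and less interferon RNA. Rises were Cyp26b1 (3.42 ± 0.12 SE, adjusted p = 1.24e-10, 468 against 43.8 CPM), Grem1 and Coch (4.51 to 5.34) and the plasma cell transcripts Igkc (7.83), Jchain (7.28) and Igha (6.89), the immunoglobulin genes being a multigene family. Falls were Ngfr (-2.54 ± 0.14 SE, adjusted p = 9.02e-09, 8.68 against 50.5 CPM) and Pgr, Krt23, Ptpn5 and Nrk (-3.20 to -2.71). TGF-beta response genes rose (9 of 16 higher, 2 lower and 5 not passing, camera adjusted p = 0.000285, adjusted p = 0.43 with an estimated correlation), led by Tagln (2.76), Ccn2 (2.04) and Acta2 (1.87). Interferon response genes fell (16 of 21 lower, 0 higher and 5 not passing, 17 and 0 adjusted over the list alone), with Ifi27l2a (-1.68) and Ifit1 (-1.58). Igfbp2 rose as well (3.35). In fibroblasts 4367 of 15592 genes passed (2073 higher and 2294 lower, 719 and 407 of them by at least 2-fold, 2678 without 0.03% 9-cis HPR replicate 1, 2841 without replicate 2, 2879 without 0.1% 9-cis HPR replicate 1). In cluster 5 alone Cyp26b1 (0.98), Igfbp2 (2.66), Tagln (1.38), Acta2 (1.26) and Coch (2.07) passed with smaller values, while Crabp1 went from 3.06 to -1.14. Igkc (0.92) did not pass without 0.1% 9-cis HPR replicate 2, nor did Jchain (6.48 to 9.08) without either 0.03% 9-cis HPR library, or Igha (0.88 to 7.35) without either 0.03% 9-cis HPR library or 0.1% 9-cis HPR replicate 2. Coch (3.87) without 0.03% 9-cis HPR replicate 1, Coch (5.58) without 0.03% 9-cis HPR replicate 2 and Igkc (8.83), Jchain (8.29) and Igha (7.89) without 0.1% 9-cis HPR replicate 1 moved by more than 1.5-fold.

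Whether 9-cis HPR and retinol differ at 0.1% was asked by direct comparison. Basal keratinocytes given 9-cis HPR carried less interferon RNA and more RNA of some differentiation genes. Falls were Isg15 (-2.73 ± 0.15 SE, adjusted p = 1.7e-11, 3.43 against 22.7 CPM) and Oasl2, Rtp4, Mmp9 and Ifi27l2a (-2.36 to -2.08), all but Mmp9 interferon-induced. Rises were Mt4 (2.91 ± 0.23 SE, adjusted p = 5.19e-09, 26.5 against 3.47 CPM) and Dapl1, Rgcc, Cst6 and Igfbp4 (1.45 to 2.51). Interferon response genes fell (18 of 21 lower, 0 higher and 3 not passing, 19 and 0 adjusted over the list alone, camera adjusted p = 4.95e-22, adjusted p = 0.0679 with an estimated correlation), led by Ifi44 (-4.50), Ifit1 (-2.83) and Usp18 (-2.66). Stress keratins and alarmins (7 of 17 lower, 1 higher and 9 not passing) included S100a9 (-2.04) and S100a8 (-1.13). Epidermal differentiation genes (11 of 24 higher, 2 lower and 11 not passing, 15 and 2 adjusted over the list alone) included Sbsn (1.09) and Krt10 (1.09). Basement membrane genes (9 of 15 lower, 0 higher and 6 not passing) included Col7a1 (-0.58). Retinoid genes (3 of 15 higher, 1 lower and 11 not passing, 5 and 1 adjusted over the list alone) included Cyp26b1 (0.42, 95% interval 0.20 to 0.64, adjusted p = 0.00865). In this class 2477 of 15569 genes passed (1146 higher and 1331 lower, 257 and 176 of them by at least 2-fold, 1253 without 0.1% 9-cis HPR replicate 1, 1444 without 0.1% Retinol replicate 1, 1443 without replicate 2). Cyp26b1 (0.21 to 0.38) did not pass without 0.1% 9-cis HPR replicate 1 or 0.1% Retinol replicate 1. Mt4 (3.66) without 0.1% Retinol replicate 1, Ifi44 (0 counts left in 1 group) without 0.1% 9-cis HPR replicate 1 and Ifi44 (-3.61) without 0.1% 9-cis HPR replicate 2 moved by more than 1.5-fold.

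In suprabasal keratinocytes 9-cis HPR came with less stress keratin and alarmin RNA and more cell cycle RNA than retinol. Rises were Mt4 (3.69 ± 0.16 SE, adjusted p = 7.79e-11, 348 against 27.2 CPM), the keratin Krt10 (1.35) and Lor, Dapl1 and Stmn1 (1.32 to 2.35). Falls were S100a9 (-2.70 ± 0.11 SE, adjusted p = 4.31e-11, 269 against 1745 CPM) and Alox8, Tmprss11g, S100a8 and Defb3 (-3.36 to -2.21). Stress keratins and alarmins fell (10 of 17 lower, 1 higher and 6 not passing, 11 and 1 adjusted over the list alone, camera adjusted p = 2.22e-10, adjusted p = 0.278 with an estimated correlation), with Lcn2 (-1.63). Cell cycle genes rose (12 of 22 higher, 1 lower and 9 not passing, 17 and 1 adjusted over the list alone), with Ccnb2 (1.33) and Birc5 (1.02). In all, 2604 of 15426 genes passed (1213 higher and 1391 lower, 267 and 188 of them by at least 2-fold, 1322 without 0.1% 9-cis HPR replicate 1, 1703 without 0.1% Retinol replicate 1, 1619 without replicate 2).

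Fibroblasts under 9-cis HPR were richer in TGF-beta response RNA than under retinol. Rises were led by transcripts of plasma cells and other cells, Igkc (8.45), Igha (7.34), Reg1 (5.18) and F13a1 (4.36) and Jchain (1052 counts against 3, 461-fold, interval 157 to 2237), Igkc and Jchain standing at 651 and 123 CPM in 9-cis HPR replicate 2 but 2.68 and 0.112 in replicate 1, and within the lists by Cyp26b1 (3.46 ± 0.12 SE, adjusted p = 5.87e-11, 468 against 42.6 CPM). Falls were the ceramide-making Smpd3 (-2.64 ± 0.08 SE, adjusted p = 4.11e-11, 39.1 against 244 CPM), Mrgprg and Dlk1 (-4.03 to -2.83) and the keratinocyte alarmins S100a9 (-2.63) and S100a8 (-2.17). TGF-beta response genes rose (11 of 16 higher, 3 lower and 2 not passing, camera adjusted p = 2e-05, adjusted p = 0.359 with an estimated correlation), led by Tagln (2.99), Ltbp2 (2.38) and Ccn2 (2.30). Heat shock and immediate early genes (12 of 19 lower, 7 higher and 0 not passing) included Hspa1b (2.33), Hspa1a (1.93) and Atf3 (-0.90), with a list mean of 0.04 against a median of -0.31. In fibroblasts 3577 of 15592 genes passed (1783 higher and 1794 lower, 749 and 353 of them by at least 2-fold, 2378 without 0.1% Retinol replicate 2). In cluster 5 alone Tagln (1.41), Ltbp2 (3.86), Ccn2 (1.5) and Cyp26b1 (0.52) passed, while F13a1 turned to -0.61. Igkc (1.54) and Igha (1.33) did not pass without 0.1% 9-cis HPR replicate 2. Igkc (9.45) and Igha (8.34) without 0.1% 9-cis HPR replicate 1, Igkc (9.15), Reg1 (5.99) and F13a1 (4.97) without 0.1% Retinol replicate 1 and Dlk1 (-3.48) without 0.1% 9-cis HPR replicate 2 moved by more than 1.5-fold.

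Whether 9-cis HPR resembles retinoic acid at 0.1% was asked directly, and basal keratinocytes did not show the alarmin, Tslp or Stra6 level of retinoic acid. Lower were Tslp (-3.25 ± 0.10 SE, adjusted p = 6.67e-16, 40.8 against 389 CPM), S100a9, S100a8 and Csf3 (-4.57 to -3.26) and the ribosomal Rn18s-rs5 (-2.93), whose copies cannot be assigned. Higher were Ccl27a (2.14 ± 0.10 SE, adjusted p = 3.6e-13, 313 against 71.2 CPM) and Col3a1, Dcn, Col1a2 and Col1a1 (2.44 to 3.04). Retinoid genes (7 of 15 lower, 5 higher and 3 not passing) included Stra6 (-5.25) and Cyp26b1 (-1.22). Alarmins and stress keratins fell (16 of 17 lower, 0 higher and 1 not passing). Dermal matrix RNA was higher in these cells (22 of 25 higher, 0 lower and 3 not passing, 23 and 0 adjusted over the list alone, camera adjusted p = 8.4e-18, adjusted p = 0.203 with an estimated correlation). In this class 5147 of 15569 genes passed (2278 higher and 2869 lower, 615 and 370 of them by at least 2-fold, 3282 without 0.1% 9-cis HPR replicate 1).

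In suprabasal keratinocytes 9-cis HPR came with less differentiation and sterol RNA than retinoic acid. Lower were S100a9 (-3.96 ± 0.12 SE, adjusted p = 1.76e-13, 269 against 4168 CPM), the heparan sulfate sulfotransferase Hs3st1 (-3.43), the multigene Lce3f and Sprr2i (-3.33 to -3.15) and Rn18s-rs5 (-3.22). Higher were Ccl27a (2.31 ± 0.07 SE, adjusted p = 8.64e-13, 164 against 33.1 CPM) and Col3a1, Col1a2, Col1a1 and Dcn (2.29 to 3.11). Epidermal differentiation genes were mostly lower (13 of 24 lower, 5 higher and 6 not passing, 15 and 6 adjusted over the list alone, camera adjusted p = 6.98e-05, adjusted p = 0.31 with an estimated correlation), with Ivl (-2.51) and Klk7 (-1.95). Sterol genes fell (14 of 18 lower, 1 higher and 3 not passing), with Scd2 (-1.94) and Lss (-1.06). Every dermal matrix gene measured was higher (25 of 25 higher, 0 lower and 0 not passing). Red cell RNA also differed (3 of 4 higher, 0 lower and 1 not passing), with Hbb-bs (2.15) and Hba-a1 (1.67), which are uncertain between family members and turned direction with 95 cells per library (-2.77 and -0.94). Altogether 5377 of 15426 genes passed (2587 higher and 2790 lower, 695 and 499 of them by at least 2-fold, 3489 without 0.1% 9-cis HPR replicate 1). Cluster 13 held 7.04% of 9-cis HPR and 34.6% of retinoic acid cells of the class, and in cluster 2 alone Ivl (-1.77), Klk7 (-1.26) and Scd2 (-1.01) passed. Hbb-bs (-0.08 to 2.17) did not pass without 0.1% 9-cis HPR replicate 1 or 0.1% Retinoic acid replicate 2, nor did Hba-a1 (-0.31 to 1.78) without 0.1% 9-cis HPR replicate 1 or either 0.1% Retinoic acid library. Lce3f (-2.47) without 0.1% 9-cis HPR replicate 1 and Lce3f (-5.08), Hbb-bs (2.93) and Hba-a1 (2.41) without 0.1% 9-cis HPR replicate 2 moved by more than 1.5-fold.

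Fibroblasts of 9-cis HPR skin held more matrix RNA than those of retinoic acid skin. Dermal matrix genes rose (22 of 26 higher, 0 lower and 4 not passing, 22 and 1 adjusted over the list alone, camera adjusted p = 8.07e-24, adjusted p = 0.321 with an estimated correlation), with Mfap4 (2.11), Eln (1.67) and Bgn (1.30). Other rises were Ccl19 (4.42 ± 0.27 SE, adjusted p = 4.11e-08, 59.6 against 2.77 CPM), Stc1, Sectm1a and F13a1 (3.78 to 4.15) and Igkc (5574 counts against 0, at least 422-fold over a floor of 3 counts per group), nearly all in 9-cis HPR replicate 2 (651 against 2.68 CPM). Lower were the B cell attractant Cxcl13 (-3.70 ± 0.11 SE, adjusted p = 6.1e-11, 191 against 2479 CPM), Mrgprg (-5.15) and the keratinocyte transcripts S100a9, S100a8 and Serpinb3a (-5.42 to -3.64). TGF-beta response genes (7 of 16 higher, 0 lower and 9 not passing) were led by Ltbp2 (3.19) and Tagln (2.88). Interferon response genes (12 of 21 higher, 1 lower and 8 not passing, 13 and 1 adjusted over the list alone) included Isg15 (1.87) and Ifi27l2a (1.34). Retinoid genes parted both ways (8 of 18 lower, 3 higher and 7 not passing, 12 and 5 adjusted over the list alone), with Rarb (-2.01) and Stra6 (-3.48) lower and Cyp26b1 (2.05) higher. Alarmins and stress keratins fell (15 of 17 lower, 0 higher and 2 not passing, 15 and 1 adjusted over the list alone). In fibroblasts 2606 of 15592 genes passed (1306 higher and 1300 lower, 432 and 418 of them by at least 2-fold). In cluster 5 alone F13a1 and Cyp26b1 turned to -1.59 and -0.14. Igkc did not pass without either 0.03% 9-cis HPR library or either 0.1% Retinoic acid library. Stc1 (3.46) and F13a1 (2.89) without 0.1% Retinoic acid replicate 1, Stc1 (5.99) and F13a1 (0 counts left in 1 group) without 0.1% Retinoic acid replicate 2, Stra6 (-2.78) without 0.1% 9-cis HPR replicate 1 and Stra6 (-4.77) without 0.1% 9-cis HPR replicate 2 moved by more than 1.5-fold.

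Retinoic acid and retinol, which end in a carboxylic acid and an alcohol, were compared at 0.1% to ask how far the 2 positive controls are alike. Basal keratinocytes under retinoic acid had more Tslp and S100a9 RNA and less interferon RNA. Rises were Tslp (3.47 ± 0.11 SE, adjusted p = 4.78e-16, 389 against 34.8 CPM), S100a9 and Hs3st1 (2.43 to 2.53) and the multigene Sprr2h (2.44) and Rn18s-rs5 (2.23). Falls were Isg15 (-2.09 ± 0.14 SE, adjusted p = 1.56e-10, 5.23 against 22.7 CPM), Rtp4 (-2.02) and the collagens Col3a1, Col1a2 and Col1a1 (-3.37 to -2.63). Retinoid genes (7 of 15 higher, 3 lower and 5 not passing, 9 and 4 adjusted over the list alone) included Stra6 (5.42), Cyp26b1 (1.64) and Crabp2 (1.5). Interferon response genes fell (16 of 21 lower, 0 higher and 5 not passing, camera adjusted p = 2.67e-17, adjusted p = 0.0679 with an estimated correlation), with Ifit1 (-2.83) and Usp18 (-2.57). Dermal matrix RNA fell in these cells (23 of 25 lower, 0 higher and 2 not passing). In this class 4329 of 15569 genes passed (2423 higher and 1906 lower, 362 and 474 of them by at least 2-fold, 2661 without 0.1% Retinol replicate 1).

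Suprabasal keratinocytes under retinoic acid had more differentiation and cell cycle RNA than under retinol. Rises were Tslp (3.13 ± 0.17 SE, adjusted p = 3.51e-10, 89.2 against 10.2 CPM), the growth factor Ereg (2.75 ± 0.10 SE, adjusted p = 6.85e-12, 181 against 27.0 CPM), Rptn and Hs3st1 (2.86 to 3.94) and the family member Lce3f (4.34). Falls were Col3a1, Col1a2 and Col1a1 (-3.64 to -2.90) and Wfdc12 and Prss53 (-2.42 to -2.01). Cell cycle genes rose (21 of 22 higher, 0 lower and 1 not passing, camera adjusted p = 5.09e-13, adjusted p = 0.278 with an estimated correlation), with Birc5 (1.5) and Mki67 (1.49). Epidermal differentiation genes rose (19 of 24 higher, 1 lower and 4 not passing, 20 and 2 adjusted over the list alone), led by Ivl (2.37), Dsc1 (1.62) and Klk7 (1.61). Sterol genes (14 of 18 higher, 1 lower and 3 not passing) included Scd2 (1.58) and Elovl6 (1.24). Antigen presentation genes fell (12 of 14 lower, 0 higher and 2 not passing, 13 and 0 adjusted over the list alone), as did dermal matrix genes (24 of 25 lower, 0 higher and 1 not passing) and, of myeloid cells, Lyz2 and Cd74 together (10.2 and 8.46 CPM against 26.7 and 21.7). In suprabasal cells 5730 of 15426 genes passed (2946 higher and 2784 lower, 621 and 727 of them by at least 2-fold). Cluster 13 held 34.6% of retinoic acid and 13.8% of retinol cells of the class, and in cluster 2 alone Ivl (1.29), Dsc1 (1.19), Klk7 (1.74) and Birc5 (1.61) passed. With 95 cells per library Wfdc12 turned direction (0.26) and did not pass.

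Fibroblasts under retinoic acid held less collagen, elastin and interferon RNA than under retinol. Dermal matrix genes fell (20 of 26 lower, 1 higher and 5 not passing, camera adjusted p = 2.51e-23, adjusted p = 0.321 with an estimated correlation), led by Eln (-1.29), Col3a1 (-1.21) and Fbn1 (-1.07). Other falls were Pgr (-2.70 ± 0.25 SE, adjusted p = 4.54e-06, 4.62 against 31.3 CPM), Trdn, Dlk1 and Greb1 (-2.92 to -2.38) and Ngfr (681 counts against 2, 58.9-fold, interval 16.2 to 487). Rises were Ereg (3.64 ± 0.34 SE, adjusted p = 6.05e-06, 21.6 against 1.73 CPM), Coch (3.20), the keratinocyte products S100a9 (2.79) and Sprr2h (2.82), and Hbb-bs of red cells (3.27). Interferon response genes (9 of 21 lower, 1 higher and 11 not passing, 10 and 1 adjusted over the list alone) included Ifi27l2a (-1.69) and Irf7 (-1.32). Alarmins and stress keratins rose (15 of 17 higher, 0 lower and 2 not passing, 16 and 0 adjusted over the list alone). Retinoid genes (6 of 18 higher, 1 lower and 11 not passing, 8 and 1 adjusted over the list alone) included Stra6 (2.83) and Cyp26b1 (1.41). In fibroblasts 2277 of 15592 genes passed (1054 higher and 1223 lower, 451 and 210 of them by at least 2-fold). In cluster 5 alone Coch was -0.10. Coch (-0.29 to 2.58) did not pass without 0.1% Retinol replicate 1 or 0.1% Retinoic acid replicate 2, nor did Hbb-bs (-0.10 to 3.29) without either 0.1% Retinol library or 0.1% Retinoic acid replicate 1. Pgr (-3.49), Trdn (-3.59) and Hbb-bs (4.27) without 0.1% Retinoic acid replicate 2, Coch (4.15) without 0.1% Retinol replicate 2, Coch (4.06) without 0.1% Retinoic acid replicate 1 and Stra6 (3.53) without 0.1% Retinol replicate 1 moved by more than 1.5-fold.

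Genes picked after their values were seen were placed on GENCODE vM21, built on GRCm38 (mm10 per the submitters' processing notes): S100a9 (ENSMUSG00000056071, chr3:90692632-90695721), Tslp (ENSMUSG00000024379, chr18:32815383-32819797), Stra6 (ENSMUSG00000032327, chr9:58063788-58153996), Cyp26b1 (ENSMUSG00000063415, chr6:84571414-84593908), Isg15 (ENSMUSG00000035692, chr4:156199424-156200818), Col3a1 (ENSMUSG00000026043, chr1:45311538-45349706), Eln (ENSMUSG00000029675, chr5:134702593-134747323) and Serpine2 (ENSMUSG00000026249, chr1:79794197-79861180).

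**Figure D2:**
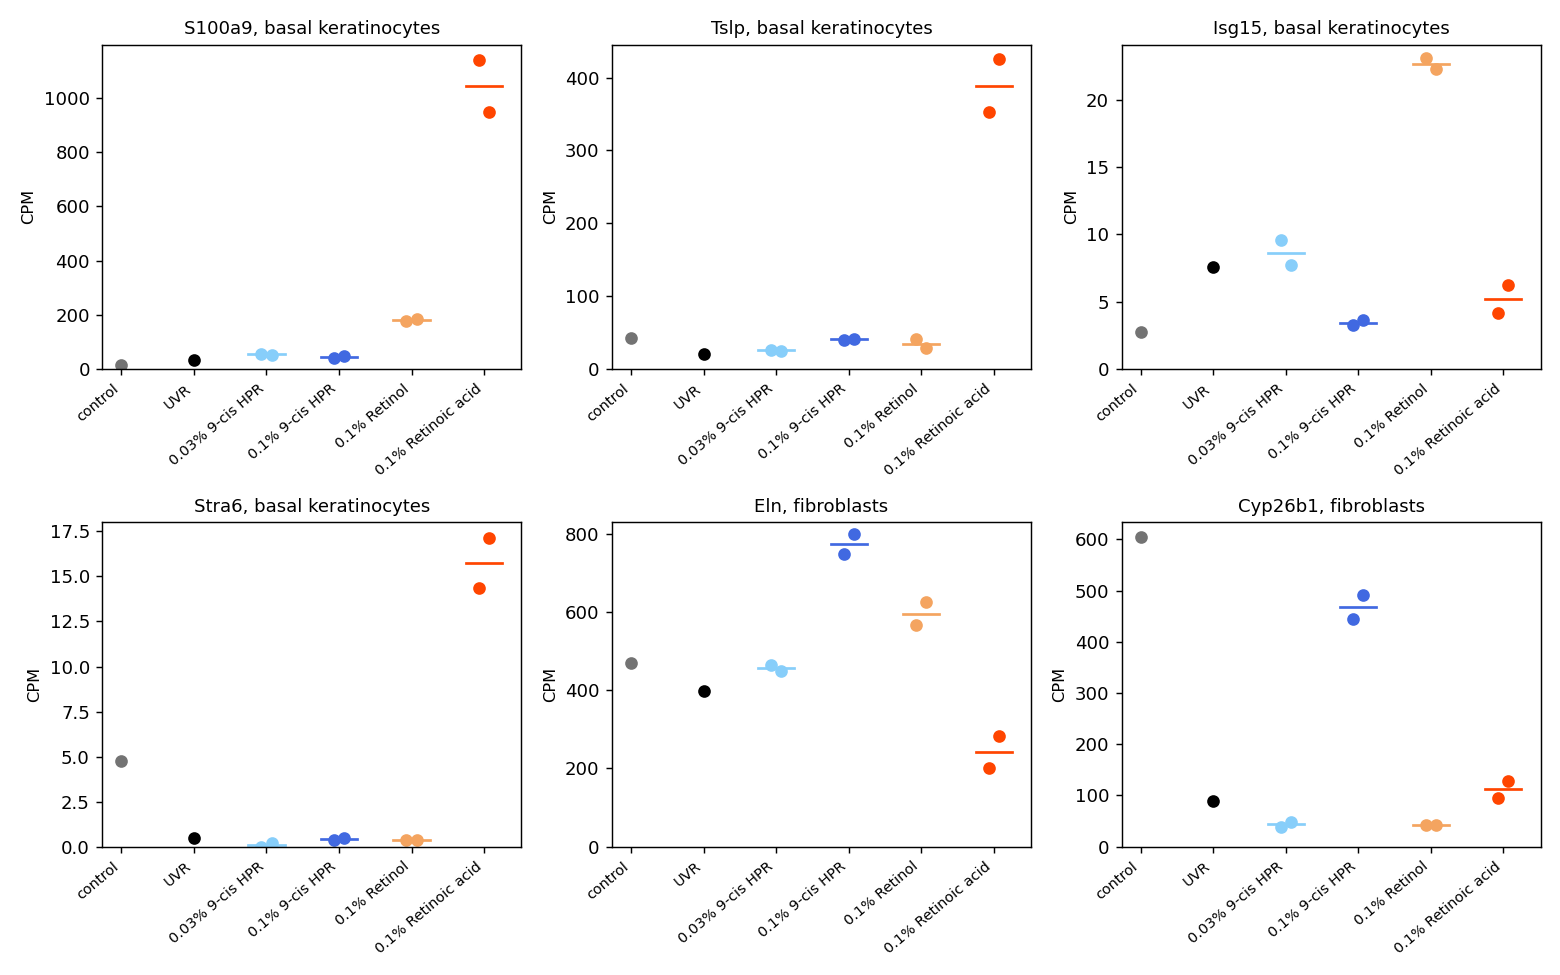
CPM of 4 genes in basal keratinocytes and 2 in fibroblasts, 1 point per library by group, lines marking the mean of 2 libraries. S100a9, Tslp and Stra6 were highest with retinoic acid and Isg15 with retinol.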

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

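The tests of a shared cell suspension, of dermal matrix genes other than Postn, Fbln1 and Sparc and of depth were chosen after the result was seen. The 2 results of the first paragraph passed a test of the difference between 2 cell classes while the list moved in opposite directions. Of 408 such differences 24 passed. For 0.1% 9-cis HPR against retinol, the mean log2 change of TGF-beta response genes was 0.708 in fibroblasts and -0.197 in basal keratinocytes, a difference of 0.905 (95% interval 0.553 to 1.257, limma with Benjamini-Hochberg adjusted p = 0.0241). For 0.03% 9-cis HPR against UVR, that of sterol and fatty acid genes was -0.253 in basal and 0.15 in suprabasal keratinocytes, a difference of -0.403 (95% interval -0.552 to -0.253, adjusted p = 0.0232). The fibroblast value is over different kinds, cluster 16 holding 41.9% of 9-cis HPR and 6.85% of retinol fibroblasts. The opposite directions rest on list calls at a preset correlation, none of which passed with the correlation estimated.

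The 2 libraries of each retinoid group had 0 genes on in 1 and off in the other, all cells summed. A library per animal cannot be told apart from pooled animals: the ratio of the median within pairs to that between groups was 0.0, but the bound set beforehand was set aside because retinoid groups differed from each other by a median of only 2.0 such genes. One shared cell suspension per pair cannot be told apart either, since the make-up by cluster matched random drawing for 0.03% 9-cis HPR (chi-square over df 0.973, p = 0.5) but not for 0.1% 9-cis HPR (2.766, p = 5.14e-06), retinol (4.792, p = 2.31e-13) or retinoic acid (158.6), and the design says nothing of pools. Spread between animals therefore stays open as untested.

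Genes of another cell type were called within classes. For dermal matrix genes in basal keratinocytes, free RNA in the droplets is argued against as the whole source: T, NK or innate lymphoid cells of the same libraries held 0.104 of the UMIs per cell of basal cells. Without Postn, Fbln1 and Sparc the median ratio was 0.413, between the bounds set, so for the other 23 genes free RNA cannot be told apart from RNA of the cells. For stress keratins and alarmins in fibroblasts of the retinoic acid libraries free RNA is consistent with the values, endothelial cells holding 0.96 of the fibroblast UMIs per cell.

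Interferon response genes were higher in basal keratinocytes of retinol than of 0.1% 9-cis HPR libraries. RNA of T, NK, innate lymphoid, Langerhans or macrophage cells is argued against, as only 1 of 18 called genes had at least 10 times the basal CPM in either immune class. Depth is argued against as well: retinoic acid replicate 2 had 2.42 times the UMIs per cell and 1.24 times the UMIs of replicate 1 but a list median of -0.013, whereas retinol had 1.36 and 1.15 times those of 9-cis HPR and a median of 1.477. An effect of the retinoids and a batch shared by each pair of libraries stay open as untested.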

How the results depend on the processing

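The fits on the largest cluster of each class, every setting for UVR against control, the shares with unnamed cells left out and the 8-library fit with no replicate block were chosen after seeing the data, and all other settings were planned. Of 397 named gene results, 298 kept their side of the threshold and, if called, their direction under every setting that gave them a value and 373 without any 1 library (390 had one with equal cells, 386 in the largest cluster and 395 without 0.1% 9-cis HPR replicate 2). RLE normalization and no low-count filter changed none, the stricter cell filter 1, doubled resolution 6, no doublet removal 10, DESeq2 20, the largest cluster 26 and equal cells 65, nearly all by ending the call. Of 60 genes named for UVR against control, 25 stayed within their counting interval under all settings and none turned direction. Of 112 shares, 40 kept their call wherever they had a value.

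Counts of called genes are given below in the order 0.03% HPR/UVR, 0.1% HPR/UVR, retinol/UVR, retinoic acid/UVR, 0.1%/0.03% HPR, HPR/retinol, HPR/retinoic acid and retinoic acid/retinol, HPR standing for 9-cis HPR. In basal keratinocytes they were 2718, 787, 1726, 3625, 3182, 2477, 5147 and 4329, and with DESeq2's Wald test 1531, 333, 762, 1890, 1771, 1042, 2647 and 2039. In suprabasal keratinocytes they were 2631, 470, 2151, 3768, 2523, 2604, 5377 and 5730, with DESeq2 1032, 207, 819, 1624, 894, 1082, 2318 and 2343, and with 95 cells from each library, the number in control, 101, 9, 110, 234, 64, 164, 464 and 342. Fibroblast counts were 2154, 905, 1620, 1212, 4367, 3577, 2606 and 2277, and with equal cells 1081, 440, 895, 615, 2026, 1783, 1537 and 1374. DESeq2 moved the fibroblast counts to 2698 for 0.1%/0.03% HPR and 2255 for HPR/retinol. In cluster 5 alone they were 526 for 0.1% HPR/UVR, 2868 for 0.1%/0.03% HPR and 1990 for HPR/retinol. With no low-count filter suprabasal calls were 803 for 0.1% HPR/UVR. With only the 2 groups compared, fewer samples, fibroblast calls were 1427 for retinoic acid/retinol. At doubled resolution suprabasal counts were 284 for 0.1% HPR/UVR and 1502 for 0.1%/0.03% HPR, and went from 1059 to 580 for UVR against control. The causes were not tested. Called gene lists went from 65, 72 and 55 in the 3 classes to 0 with an estimated correlation between genes.

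The percent of calls that were higher moved in suprabasal 0.1% HPR/UVR from 44.3 to 54.7 with no filter and 55.6 with equal cells, in retinoic acid/UVR from 53.5 to 65.3 with DESeq2 and 64.1 with equal cells, in HPR/retinoic acid from 48.1 to 37 and 36.4, in retinoic acid/retinol from 51.4 to 61.7 with DESeq2, and in fibroblast 0.1% HPR/UVR from 50.4 to 39.1 with no doublet removal. With equal cells, values turned direction in suprabasal keratinocytes for Lor (-2.26) and Flg (-1.93) in 0.03% HPR/UVR, Il19 (0.77) in 0.1% HPR/UVR, Hbb-bs (-2.77) and Hba-a1 (-0.94) in HPR/retinoic acid and Wfdc12 (0.26) in retinoic acid/retinol. In cluster 5 alone Acta2 (-0.44) turned in 0.1% HPR/UVR, Crabp1 (-1.14) in 0.1%/0.03% HPR, F13a1 (-0.61) in HPR/retinol and (-1.59) in HPR/retinoic acid, Cyp26b1 (-0.14) in HPR/retinoic acid and Coch (-0.10) in retinoic acid/retinol. Over the fits without 1 library, suprabasal Hbb-bs (-0.084 to 2.93) and Hba-a1 (-0.31 to 2.41) in HPR/retinoic acid and fibroblast Hbb-bs (-0.095 to 4.27) and Coch (-0.29 to 4.15) in retinoic acid/retinol turned direction. The cause was not tested.

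Without 1 library at a time, the 8 counts, in the same order, ranged over 1714 to 3165, 476 to 1099, 1089 to 2084, 3267 to 3616, 1731 to 3664, 1253 to 2928, 3282 to 4981 and 2661 to 4171 in basal keratinocytes, 1604 to 3097, 298 to 658, 1468 to 2575, 3382 to 3926, 1018 to 3066, 1322 to 3060, 3489 to 5174 and 3822 to 5769 in suprabasal keratinocytes and 1346 to 2798, 539 to 1373, 1101 to 2171, 892 to 1311, 2678 to 5034, 2378 to 4261, 1770 to 2466 and 1519 to 2060 in fibroblasts. The lone sample left in a group is then assumed to vary like the others, and leaving out UVR or control gives no value for their comparisons. Calls of a share went from 66 to between 44 and 100, the most without 0.1% Retinoic acid replicate 1. TMM factors gave 84 and turned the log2 share of blood endothelium (-0.32) and of Langerhans or macrophage cells (-0.15) in HPR/retinoic acid and of neutrophils (0.40) in retinoic acid/retinol.

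The replicate numbers were not taken to pair the samples: of 18 correlations of deviations between same-numbered libraries (-0.014 to 0.23), 3 were above 0.1, all of them between retinol and retinoic acid. Over the 8 numbered libraries the replicate block gave 3466, 2674, 5281 and 4570 basal calls for the 4 comparisons between retinoid groups, against 3207, 2424, 5043 and 4276 with no block, moved no other count by over 1.5-fold, changed no named call and left 39 share calls.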

Other observations

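All values here were picked after the data were seen and carry no test. Control skin held a population of T, NK or innate lymphoid cells that the other libraries nearly lacked: cluster 22, marked by Cd7, Xcl1 and Trdc, had 717 of its 877 cells in control, 4 in UVR and at most 62 in any other. Trdc is part of the T cell receptor delta chain.

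Cluster 4, with Rn18s-rs5, Lars2 and Sprr2h on top and a median of 1265 UMIs, stayed unnamed and made up 40.5% of retinoic acid replicate 1 and 8.03% of replicate 2. Over all cells of a library, Hbb-bs of red cells stood at 0.466 CPM in control and 0.737 in UVR and at 25.7 to 70.5 in the 8 treated libraries, the split between globin copies being uncertain. Igkc of plasma cells ranged from 0.687 to 189 CPM, the highest and lowest being in 0.03% 9-cis HPR and retinoic acid libraries.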
